A study of Mus musculus with 8 samples.

How the data were processed

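Gene expression was measured by bulk RNA sequencing of subcutaneous tumours grown from CT26, a mouse colon carcinoma cell line, in male mice. Per the labels, 4 tumours came from mice given PBS (control) and 4 from mice given propranolol, a blocker of beta-adrenergic receptors, by daily injection into the peritoneum from the time the tumours reached 70 to 100 cubic millimetres. Tumours were flash frozen and total RNA was extracted, per the labels' protocols. The dose and the day of collection are not given in the sources used here. The design text speaks of duplicates, whereas the sample titles number 4 tumours in each group, and the 4 numbered tumours per group were used as replicates. No label says whether each numbered sample came from its own animal, so the p-values measure the spread between these samples.

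The deposited table holds 14133 genes, each with the raw read count and the FPKM in every tumour, per the file headers. The authors' columns also give a log2 fold change, a p-value and an adjusted p-value for propranolol against control, per the file headers. The submitters' processing notes name fastp 0.19.3, HISAT2 2.1.0, StringTie 1.3.4d, featureCounts 1.6.2, DESeq2 1.22.1, edgeR 3.24.3 and the genome build GRCm39, without saying what each tool did. Whether counting used strand, and how reads shared by near-identical genes were counted, is not given in the sources used here. Every gene of the deposited count table exceeds 1 CPM in at least 2 of the 8 libraries, so a gene below that level is not analysed here. The FPKM values moved between libraries in step with the column totals of the deposited counts. The log2 fold changes, p-values and adjusted p-values in the authors' deposited table matched a DESeq2 Wald test run here on the same counts within 1e-05, except for 46 genes to which DESeq2 gave no p-value and the table a p-value of 1. The table marks 95 genes as up and 17 as down; all 112 have an unadjusted p-value under 0.05 and a log2 fold change of at least 1 in size.

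The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3) on the counts, with TMM normalisation, the filterByExpr filter, robust dispersion estimates and Benjamini-Hochberg adjustment at 0.05. The filter left 14006 genes and removed 127. Log2 fold changes of single genes are from this fit and carry its standard error. CPM values use the TMM-scaled library sizes, except those of the skeletal muscle list sum and of muscle genes outside the list, which use the library totals as they are. Before the data were examined, 30 gene lists were fixed for immune cells, stroma, other tissues, signalling pathways and RNA quality, holding 424 different genes, of which 361 are in the table. Of these lists, 28 had at least 5 tested members and were tested with limma's camera (limma 3.58.1, two-sided) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. The same lists were tested with camera at an estimated correlation and with fry. A list score is the mean over members of log2 CPM minus the gene's mean over the 8 tumours, and the list effect is the difference between the group means of that score. Scores were compared with an exact two-sided permutation test, whose smallest possible p with 4 against 4 is 0.0286.

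The genes named in the text follow a rule set at the same time. It takes the 10 genes with the largest rise and the 10 with the largest fall among genes past the threshold, a fixed set of T cell and exhaustion genes, and up to 4 members per list past the threshold. Where no member of a list passed it takes the 2 members with the smallest p, and where fewer than 5 genes passed in a direction it takes the 5 with the smallest p at a mean log2 CPM of at least 1, predicted genes left out. Since no gene passed, the 80 named genes come from the later parts of the rule. Not every gene the rule takes is reported.

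Total counts per library were between 15483409 and 17511937. A check for copies of a library within a group found none. Copies would give a chi-square per degree of freedom near or below 1 over genes, and the smallest within a group was 12.7. Pairs between the groups were not checked in this way, and their highest Pearson correlation of log2 CPM was 0.989, against 0.986 within a group. In counts simulated for propranolol against control over 14006 genes with the real means, dispersions and library sizes, the edgeR step recovered 57% of 100 genes changed 2-fold and 88% of 100 genes changed 4-fold, and called 10 unchanged genes. In the same kind of simulation with independent genes, camera called 11 of 14 lists shifted by 0.5 on the log2 scale. It called 1 of 10 unshifted lists that held no shifted gene, and 0 lists when nothing was shifted anywhere. Members of several real lists move together, with estimated correlations up to 0.968 (interferon gamma response), so these rates do not carry over to them.

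Control and propranolol tumours carry the same numbers, 1 to 4. The deviations of same-numbered tumours from their group means correlated at 0.190, 0.311, 0.508 and 0.277 over genes, all above the limit of 0.1 set for treating the numbers as pairs. The pairing therefore rests on the data and on the shared numbers, since no label says what a number stands for. The limit does not single out the numbers: of the 24 ways to pair the tumours, 4 had every correlation above it and 2 had a mean at least as high as that of the numbers, 0.322. The highest mean, 0.379, paired control tumour 1 with propranolol tumour 4 and control tumour 4 with propranolol tumour 1. The block was not fitted under another pairing, and 4 of the 8 tumours correlated best with their own number. The fit with the number as a block lowered the common biological coefficient of variation from 24.5% to 17.5%.

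The alternatives were DESeq2 1.42.0, limma-voom with and without sample quality weights, RLE factors or library size alone, no low-count filter or a mean CPM of at least 10, non-robust dispersions, other thresholds, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1), a prior count of 0.5, the replicate block, and leaving out each tumour in turn.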

Results

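The data are gene expression profiles of 8 CT26 tumours, 4 from control mice and 4 from mice given propranolol. Library totals were 15483409, 17467604, 17511937 and 17279100 counts for control tumours 1 to 4 and 17201729, 16711003, 16773175 and 16570218 counts for propranolol tumours 1 to 4, and 14006 genes were tested. The series title names T cell exhaustion and tumour growth, so the comparison asks which genes, and in particular which T cell genes, differ between propranolol and control tumours.

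On average, propranolol tumours held more transcripts of T cells, of cytotoxic effectors, of inhibitory receptors, of MHC class II presentation and of the interferon gamma response than control tumours, and fewer erythroid, cell cycle and mitochondrially encoded transcripts. These are the 8 lists that passed camera at the preset correlation, and 0 lists passed with an estimated correlation. The estimated correlations of the 8 lists were 0.424 to 0.968, so the preset value of 0.01 was too low for them. Members of a list moved together, so a count of members with the same sign is not a count of separate observations. The 5 immune lists differed by 0.51 to 0.89 on the log2 scale, but the tumours within a group differed by more than that. The T cell list ranged from -1.24 to 0.21 in control tumours and from -2.15 to 1.88 in propranolol tumours. No single gene passed the threshold. With edgeR's quasi-likelihood test 0 genes were higher and 0 lower at an adjusted p under 0.05, and the smallest adjusted p was 0.999. At an unadjusted p under 0.05, edgeR gave 273 genes (173 higher, 100 lower), where chance alone would give 700.3. DESeq2 also gave 0 genes past the threshold and 337 at an unadjusted p under 0.05. With the replicate number as a block, edgeR gave 0 genes past the threshold and 717 at an unadjusted p under 0.05.

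All 17 tested T cell markers had a higher fitted level in propranolol tumours, and 0 of them passed, either over all genes or adjusted over the list alone. Cd8a, which encodes a chain of the co-receptor of cytotoxic T cells (ENSMUSG00000053977, chromosome 6 from 71350411 to 71356157), averaged 6.37 ± 4.20 CPM in control and 28.3 ± 25.9 CPM in propranolol tumours (SD, n = 4 each). Its log2 fold change was 2.16 with a standard error of 1.01, and 3 of 4 propranolol tumours lay above every control tumour. Of these, propranolol tumour 2 at 12.6 CPM lay only just above control tumour 1 at 12.3 CPM. Cd3d, a subunit of the T cell receptor complex, had a log2 fold change of 2.04 (SE 0.82) and Cd8b1, the partner chain of Cd8a, one of 2.14 (SE 0.92). Cd4, the co-receptor of helper T cells, differed less, with 2.04 ± 1.16 CPM in control and 2.67 ± 1.53 CPM in propranolol tumours (SD, n = 4). The list as a whole was higher by 0.81 (camera adjusted p = 0.00206, but adjusted p = 0.760 with the estimated correlation, 0.924).

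Of the 14 tested exhaustion and inhibitory receptor genes, 13 had a higher fitted level with propranolol and 0 passed, over all genes or adjusted over the list alone. Pdcd1, which encodes the checkpoint receptor PD-1 (ENSMUSG00000026285, chromosome 1 from 93966027 to 93980278), averaged 2.46 ± 1.57 CPM in control and 10.2 ± 10.3 CPM in propranolol tumours (SD, n = 4), a log2 fold change of 2.05 with a standard error of 1.04, and 2 of 4 propranolol tumours lay above every control tumour. Lag3, another inhibitory receptor, had a log2 fold change of 1.85 (SE 0.79), Havcr2, which encodes TIM-3, one of 1.04 (SE 0.59), and Tox, a transcription factor of exhausted T cells, one of 1.56 (SE 0.95). The inhibitory receptor genes Tigit and Ctla4 were close to equal on average, with log2 fold changes of 0.09 (SE 0.23) and 0.17 (SE 0.87). Tigit lay between 8.93 and 17.3 CPM in every tumour, while Cd8a spanned 1.05 to 57.0 CPM. Which cells held the Tigit transcripts was not tested. The sign for Ctla4 turned with limma-voom and with the block, and the standard error is several times the value. The list was higher by 0.54 (camera adjusted p = 0.0153, but adjusted p = 0.760 with the estimated correlation, 0.424).

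The 15 cytotoxic effector genes were higher in fitted level without exception, and 0 passed, over all genes or adjusted over the list alone. Gzmb, which encodes granzyme B, averaged 21.2 ± 16.7 CPM in control and 52.1 ± 46.3 CPM in propranolol tumours, and Prf1, which encodes perforin, 14.4 ± 12.2 and 41.4 ± 40.5 CPM (SD, n = 4). Ifng, the gene of interferon gamma, had a log2 fold change of 2.34 (SE 1.21), with 0 counts in propranolol tumour 3. Gzmk, another granzyme gene, and the chemokine gene Ccl5 had log2 fold changes of 1.63 (SE 0.55) and 1.76 (SE 0.83). The list was higher by 0.86 (camera adjusted p = 0.00301, but adjusted p = 0.760 with the estimated correlation, 0.881). Regulatory T cell markers differed by 0.13 (camera adjusted p = 0.296), and Foxp3, their defining transcription factor, averaged 1.13 ± 0.358 CPM in control and 1.19 ± 1.03 CPM in propranolol tumours (SD, n = 4). Il2ra, the interleukin-2 receptor alpha chain, and Ikzf4, a transcription factor of regulatory T cells, had log2 fold changes of 0.74 (SE 0.44) and 0.32 (SE 0.29).

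**Figure D1:**
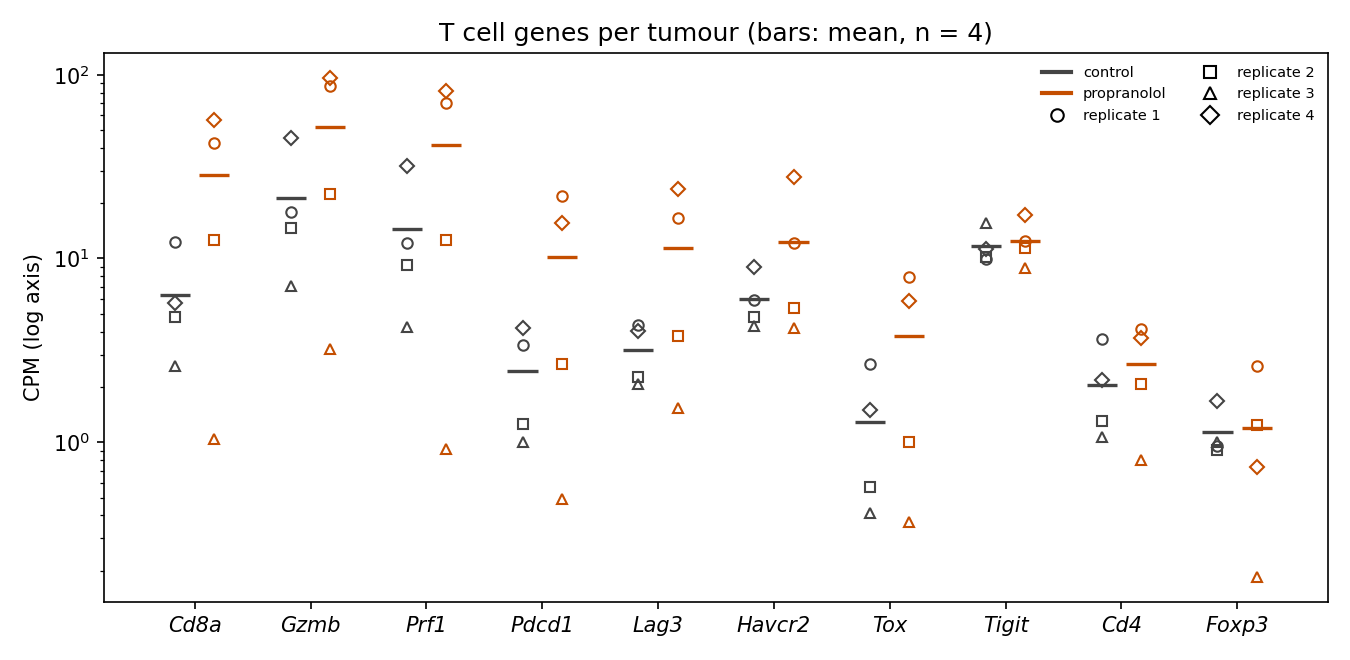
Each point is the level of a gene in 1 tumour, in CPM on a log axis, for T cell genes; horizontal bars are group means (n = 4) and symbols give the replicate number. Propranolol tumours 1 and 4 lie above every control tumour for Cd8a, Pdcd1, Lag3 and Tox, while propranolol tumour 3, at 1.05 CPM of Cd8a and 0.493 CPM of Pdcd1, lies below every control tumour for both.

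Antigen presentation and the interferon gamma response moved with the T cell genes. All 9 MHC class II presentation genes had a higher fitted level in propranolol tumours, among them H2-Ab1, a class II chain (105 ± 67.1 CPM in control, 318 ± 283 CPM in propranolol, SD, n = 4), and H2-Ob, a regulator of class II peptide loading (log2 fold change 1.3, SE 0.47). All 20 interferon gamma response genes were higher too. They include Ido1, an enzyme that breaks down tryptophan (log2 fold change 2.53, SE 0.93), and Cd274, which encodes the PD-1 ligand PD-L1 (36.0 ± 9.88 CPM in control, 82.4 ± 65.6 CPM in propranolol, SD, n = 4). Members past the threshold numbered 0 in both lists, over all genes or adjusted over the list alone. Camera gave adjusted p = 0.00347 for the MHC class II list, a difference of 0.89, but adjusted p = 0.760 with the estimated correlation, 0.907. It gave adjusted p = 0.0123 for the interferon gamma list, a difference of 0.51, but again adjusted p = 0.760 with the estimated correlation, 0.968.

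With any 1 tumour left out these 5 immune lists kept their sign, but their calls depended on which tumour was left out. Their named genes also kept their sign, except Tigit and Ctla4, though the sizes moved. Leaving out 1 tumour took the log2 fold change of Havcr2 as low as 0.27, of Ccl5 to 0.67 and of Cd274 to 0.67. The lowest values in these fits were 0.90 for Tox, 1.21 for Ifng and Lag3, 1.35 for Pdcd1, 1.56 for Cd8a and 1.82 for Ido1. Over all alternatives, the lowest values were 0.94 for Ifng, 0.97 for Lag3, 0.99 for Pdcd1, 1.195 for Cd8a and 1.37 for Ido1. For Tox, Havcr2, Ccl5 and Cd274 no alternative went below the leave-out values. The sizes for Ifng, Lag3, Pdcd1, Cd8a and Ido1 thus depended on the processing as well as on single tumours. None of the 5 lists passed camera without control tumour 3 (differences of 0.35 to 0.56), without propranolol tumour 1 (0.13 to 0.53) or without propranolol tumour 4 (0.06 to 0.34). Without control tumour 2 the exhaustion and interferon gamma lists were lost and 3 of the 5 remained past the threshold, and without propranolol tumour 3 the differences grew to 1 to 1.75.

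**Figure D2:**
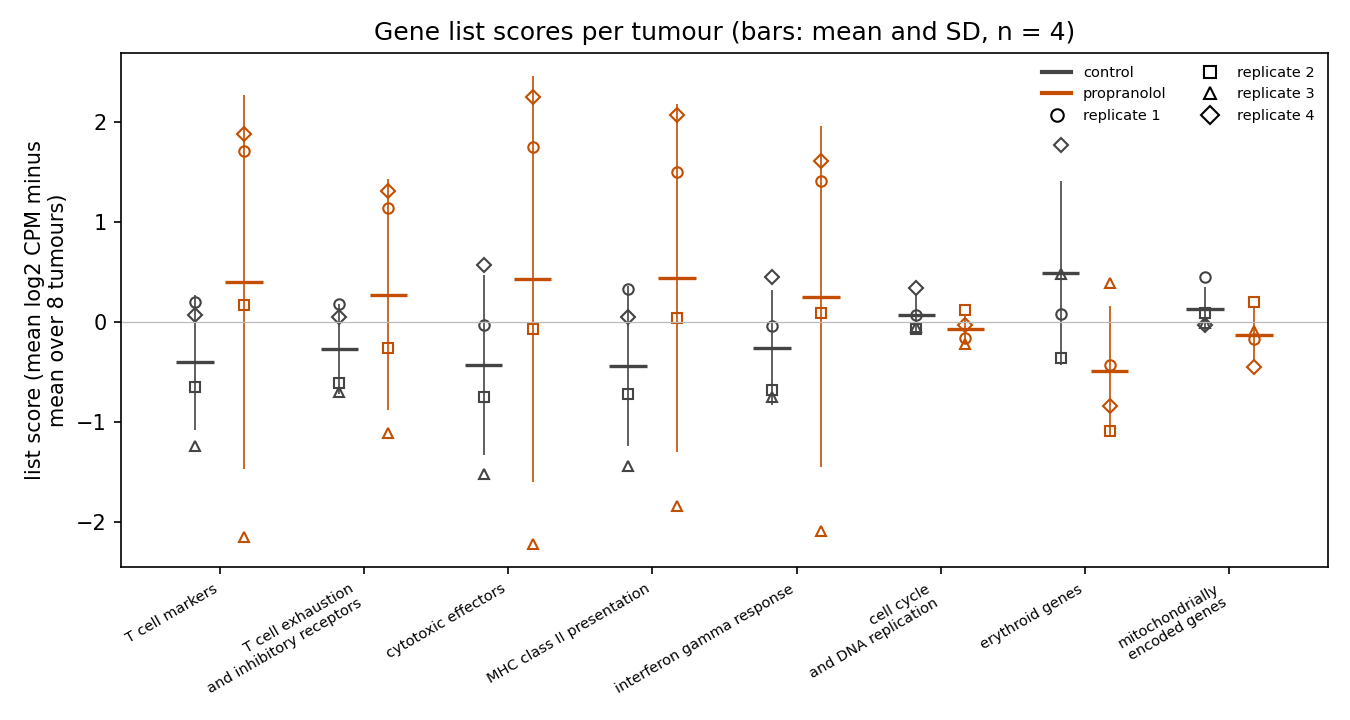
Each point is the score of a gene list in 1 tumour (mean log2 CPM of its members minus their mean over the 8 tumours), for the 8 lists past camera's threshold; bars are group means and vertical lines the SD (n = 4). For the 5 immune lists, propranolol tumours 1 and 4 have the highest scores and propranolol tumour 3 the lowest in the series.

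A further 4 immune lists had higher averages in propranolol tumours and, with all 8 tumours, passed with the replicate block and not without it. NK cell markers, 8 of 8 with a higher fitted level, differed by 0.75 (camera adjusted p = 0.0527; with the replicate block 3.18e-04, but adjusted p = 0.629 with the block and an estimated correlation), with Klrc1 and Klrc2, 2 closely related receptor genes of NK cells, at log2 fold changes of 1.67 (SE 0.84) and 1.82 (SE 0.97). The type I interferon response differed by 0.24 (camera adjusted p = 0.103; with the block 1.83e-05, but adjusted p = 0.629 with an estimated correlation), with Oasl2 and Rtp4, both interferon-induced, at 0.61 (SE 0.51) and 0.58 (SE 0.54). Dendritic cell markers differed by 0.30 (camera adjusted p = 0.313; with the block 0.0174, but adjusted p = 0.629 with an estimated correlation) and macrophage markers by 0.16 (camera adjusted p = 0.133; with the block 0.0174, but adjusted p = 0.678 with an estimated correlation). Among their members, H2-DMb2, a chaperone of class II loading, had a log2 fold change of 1.40 (SE 0.63), Fscn1, an actin-bundling protein of mature dendritic cells, -0.35 (SE 0.19), and the complement genes C1qa and C1qc 0.47 (SE 0.27) and 0.44 (SE 0.27). These averages also moved with single tumours: leaving out 1 tumour gave 0.22 (without propranolol tumour 4) to 1.46 (without propranolol tumour 3) for NK cell markers, which passed camera in 4 of the 8 fits without the block. The ranges were 0.0679 to 0.52 for dendritic cell markers, 0.0205 to 0.33 for macrophage markers and -0.0308 to 0.55 for the type I interferon response, which passed in 1, 1 and 3 of the fits. With an estimated correlation 0 lists passed in any of these fits. With the block 12 lists passed camera in place of 8, and the 4 added were these; with an estimated correlation 0 lists passed in either fit, so none of the calls holds there. The smallest adjusted p was 0.760 in the fit without the block. Fry, which tests whether a list's genes move one way on balance, gave 0 lists (smallest adjusted p 0.864). Exact permutation of the list scores, which does not use the number pairs, gave no p under 0.114. Within the 4 number pairs, 3 lists differed in 1 direction throughout, where chance gives 3.5: erythroid genes and alternatively activated myeloid genes lower, and the type I interferon response higher. A sign-flip test over 4 pairs has no p below 0.125; the count was made after the scores were seen.

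B and plasma cell markers (0.14, camera adjusted p = 0.806), mast cell markers (0.33, camera adjusted p = 0.212), neutrophil and granulocytic markers (0.23, camera adjusted p = 0.513) and alternatively activated myeloid genes (-0.20, camera adjusted p = 0.209) did not pass. Jchain and Igkc, which encode antibody components, had log2 fold changes of 1.10 (SE 0.83) and 1 (SE 0.91). The mast cell protease genes Cpa3 and Tpsb2 had 0.90 (SE 0.66) and 0.77 (SE 0.58). Hdc, the histamine-forming enzyme, and Csf3r, the G-CSF receptor, had 0.76 (SE 0.47) and 0.74 (SE 0.45). Folr2 and Clec10a, both used as markers of alternatively activated macrophages, went opposite ways, with -0.48 (SE 0.23) and 0.50 (SE 0.30). Without propranolol tumour 3, mast cell markers (0.79, adjusted p = 3.12e-04), B and plasma cell markers (0.75, adjusted p = 0.0242) and regulatory T cell markers (0.48, adjusted p = 0.00539) passed camera, and alternatively activated myeloid genes did without propranolol tumour 1 (-0.32, adjusted p = 0.0117); none did with an estimated correlation.

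Erythroid genes were lower in propranolol tumours (list difference -0.99, camera adjusted p = 2.24e-04, but adjusted p = 0.760 with an estimated correlation). All 5 tested members had a lower fitted level and 0 passed, over all genes or adjusted over the list alone. Hbb-bs, a beta-globin gene with a near-identical neighbour, averaged 44.3 ± 30.4 CPM in control and 17.8 ± 9.41 CPM in propranolol tumours (SD, n = 4), and Alas2, the erythroid enzyme of haem synthesis, had a log2 fold change of -0.93 (SE 0.34). Control tumour 4 had the highest erythroid score, 1.77, and also held skeletal muscle transcripts that the other tumours largely lacked. Without it the list difference was -0.56, past camera's threshold at the preset correlation (adjusted p = 0.00290), but adjusted p = 0.912 with an estimated correlation. Skeletal muscle markers differed by -0.96 (camera adjusted p = 0.115). The list turned to 0.63 without control tumour 4, and passed camera without control tumour 1 (-1.78, adjusted p = 0.00375), control tumour 2 (-1.78, adjusted p = 0.00279) or propranolol tumour 1 (-1.70, adjusted p = 0.00312), though 0 lists passed in these fits with an estimated correlation. Atp2a1, the calcium pump of fast muscle, reached 82.5 CPM in control tumour 4 and at most 3.78 CPM elsewhere, and Ckm, the muscle creatine kinase, 55.3 CPM and at most 2.24 CPM.

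Cell cycle and DNA replication genes were lower by a small amount (list difference -0.15, camera adjusted p = 4.08e-04, but adjusted p = 0.760 with an estimated correlation). Of 21 members, 19 had a lower fitted level and 0 passed, over all genes or adjusted over the list alone. Rrm2, a subunit of ribonucleotide reductase, averaged 214 ± 29.2 CPM in control and 171 ± 31.9 CPM in propranolol tumours, and Ccna2, which encodes cyclin A2, 197 ± 24.8 and 165 ± 18.8 CPM (SD, n = 4). Without control tumour 4 the difference was -0.06 and the list no longer passed (adjusted p = 0.251).

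Mitochondrially encoded genes, read here as a sign of RNA quality as well as of respiration, were lower (list difference -0.25, camera adjusted p = 0.00163, but adjusted p = 0.760 with an estimated correlation). Of 12 members, 11 had a lower fitted level and 0 passed, over all genes or adjusted over the list alone, with mt-Atp6 at a log2 fold change of -0.47 (SE 0.21) and mt-Nd2 at -0.35 (SE 0.18). The share of counts from the mitochondrial genome was 1.78% to 2.40% in control and 1.31% to 2.11% in propranolol tumours. The list did not pass without control tumour 1 (-0.12, adjusted p = 0.169) or without propranolol tumour 4 (-0.11, adjusted p = 0.149).

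Genes of the beta-adrenergic signalling pathway were near equal in the 2 groups. The 19 tested members of the list had a mean difference of 0.00430, a median of -0.01 and a camera direction of down (adjusted p = 0.796), so the mean and the test differ in sign. Prkaca, a catalytic subunit of the cAMP-dependent kinase, had a log2 fold change of -0.16 (SE 0.10) and Arrb1, which encodes a beta-arrestin, 0.21 (SE 0.18). The cAMP-induced immediate early genes differed by -0.08 (camera adjusted p = 0.386), with Ier2 and Crem, 2 of the early-response genes, at -0.48 (SE 0.21) and 0.52 (SE 0.24). Without propranolol tumour 3 the latter list passed camera (-0.22, adjusted p = 0.0252), but 0 lists passed there with an estimated correlation.

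The remaining lists did not pass. Hypoxia response differed by 0.18 (camera adjusted p = 0.313) and glycolysis by 0.10 (camera adjusted p = 0.231). Car9, a carbonic anhydrase induced by low oxygen, reached 136 CPM in propranolol tumour 3 and 6.15 to 36.1 CPM in the other 7, and the hypoxia-induced peptide gene Adm had a log2 fold change of 0.55 (SE 0.50). Without propranolol tumour 3 the hypoxia list turned to -0.27 and passed camera (adjusted p = 0.0463). It passed in the other direction without control tumour 3 (0.47, adjusted p = 0.0145), without propranolol tumour 1 (0.46, adjusted p = 0.00350) and without propranolol tumour 2 (0.43, adjusted p = 0.0171). Glycolysis passed in the same 3 fits, at 0.21 (adjusted p = 0.0280), 0.25 (adjusted p = 0.00157) and 0.21 (adjusted p = 0.0161), and turned to -0.12 without propranolol tumour 3. With an estimated correlation 0 lists passed in any of these fits. The glycolytic enzyme genes Pfkp and Hk1 had log2 fold changes of 0.37 (SE 0.14) and 0.28 (SE 0.15). Angiogenic factors differed by 0.03 (camera adjusted p = 0.513; Fgf2 0.23, SE 0.21; Hgf 0.40, SE 0.39) and endothelial markers by -0.02 (camera adjusted p = 0.945; Kdr -0.24, SE 0.19; Plvap 0.16, SE 0.13). The fibroblast and matrix list differed by -0.13 (camera adjusted p = 0.326), with the matrix genes Postn and Lum at -0.78 (SE 0.52) and -0.32 (SE 0.24). It passed camera without propranolol tumour 3 (-0.25, adjusted p = 0.0353), as did stress and dissociation genes (-0.34, adjusted p = 0.0118), which also passed without control tumour 2 (-0.25, adjusted p = 0.0386); none of these calls held with an estimated correlation. The p53 and apoptosis list differed by -0.00248 (camera adjusted p = 0.386), with Eda2r and Fas, both of the TNF receptor family, at -0.43 (SE 0.16) and 0.73 (SE 0.41). Stress and dissociation genes differed by -0.12 (camera adjusted p = 0.231; Ddit4 0.86, SE 0.50; Hspb1 -1.24, SE 0.89) and adipocyte markers by 0.15 (camera adjusted p = 0.336; Lipe 0.28, SE 0.10; Cfd 1.36, SE 1.03). In each of the 20 lists outside the 8 past camera, 0 members passed when adjusted over the list alone. Epithelial genes and skin keratinocyte markers had 3 tested members each and were not tested as lists. Krt8 and Krt18, a pair of simple-epithelium keratin genes, had log2 fold changes of -1.10 (SE 1.11) and -0.38 (SE 0.41), and the skin genes Krt10 and Trp63 had 0.15 (SE 0.20) and 0.30 (SE 0.49).

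The genes with the smallest p-values were not T cell genes. C1rb, a complement protease gene on chromosome 6 from 124547253 to 124558130 (ENSMUSG00000098470, protein-coding), averaged 3.54 ± 0.665 CPM in control and 11 ± 5.3 CPM in propranolol tumours (SD, n = 4). Its log2 fold change was 1.63 (SE 0.37). All 4 propranolol tumours lay above all 4 controls, but propranolol tumour 2 (4.26 CPM, 72 counts) only just above control tumour 4 (4.20 CPM, 73 counts). The edgeR adjusted p of C1rb was 0.999. In the authors' deposited table, its adjusted p of 0.259 is the smallest. C1rb has a close relative, C1ra, so reads may be split between them. Malat1, a nuclear long non-coding RNA on chromosome 19 from 5845718 to 5852700 (ENSMUSG00000092341), averaged 424 ± 97.1 CPM in control and 683 ± 112 CPM in propranolol tumours, a log2 fold change of 0.69 (SE 0.19). Spata13, a guanine nucleotide exchange factor gene on chromosome 14 from 60871450 to 61002005, had 0.47 (SE 0.12). Hdhd5 on chromosome 6 from 120486455 to 120508280 had 0.50 (SE 0.13), and Gas7 on chromosome 11 from 67345917 to 67579816 had 0.35 (SE 0.10). All coordinates are on GRCm39 as the deposited table gives them, and the genes are protein-coding except Malat1.

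In the lower direction, Get1, which encodes a subunit of the insertion machinery for tail-anchored membrane proteins, lies on chromosome 16 from 95946607 to 95959052 and had 23.8 ± 1.74 CPM in control and 18.8 ± 1.04 CPM in propranolol tumours (SD, n = 4). Lrrc28 on chromosome 7 from 67163158 to 67295016 had a log2 fold change of -0.51 (SE 0.15), and Gask1b on chromosome 3 from 79791840 to 79853587 one of -0.49 (SE 0.16). Stk40, a kinase-like gene on chromosome 4 from 125997750 to 126034822, had -0.33 (SE 0.11). B4galt7, a galactosyltransferase gene of proteoglycan assembly on chromosome 13 from 55747709 to 55758256, had -0.32 (SE 0.11). None of these 10 genes passed in edgeR, where each had an adjusted p of 0.999.

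Over all genes, the tumours did not separate by treatment. The first principal component of log2 CPM held 46.8% of the variance and had T cell and cytotoxic genes among its most negative loadings (mean loading percentiles 0.935 and 0.660), with propranolol tumours 4 and 1 at one end and propranolol tumour 3 and control tumour 3 at the other (exact permutation p = 0.514 for the groups). The second component held 15.5% and set control tumour 4 apart (exact permutation p = 0.457).

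**Figure D3:**
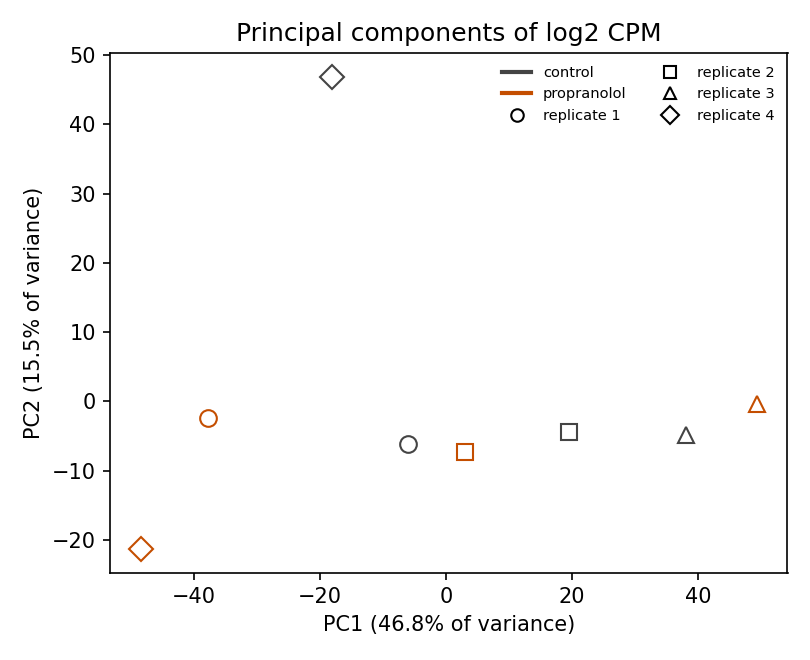
Each point is a tumour on the first and second principal components of log2 CPM over the tested genes, with the share of variance on each axis; colours give the group and symbols the replicate number. Control tumour 4 lies at 46.9 on the second component, and propranolol tumours span the first from -48.4 to 49.4.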

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

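The tests of skeletal muscle transcripts, of the slopes on the T cell list, and of the erythroid list without control tumour 4 by an estimated correlation and by permutation were chosen after the results they concern were seen; the other tests in this part were set before.

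In 6 of 220 groups of 4 values, 1 tumour stood apart from the other 3 by more than 0.829 of the group's range; chance gives about 1 in 20. Control tumour 4 was low for Hdhd5 (0.850 of the range) and for Malat1 (0.857; 280 CPM against at least 454 CPM in the other controls) and high for Foxp3 (0.845; 1.67 CPM against at most 1 CPM). Control tumour 2 was high for Get1 (0.884), propranolol tumour 1 was low for Lrrc28 (0.882), and the library of control tumour 1 was the smallest of its group (0.885; 15483409 counts).

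The counts of calls can be set against other splits of the same 8 tumours. The real split gave 0 genes past edgeR's threshold, which all 35 splits into 4 and 4 reach by definition, so this count tests nothing; the highest of the other splits gave 585. For genes at an unadjusted p under 0.05, 28 of the 35 splits gave at least the real 273 (highest other 3193), and for lists past camera 24 of 35 gave at least the real 8 (highest other 20). Chance cannot be excluded for the last 2 counts. The split with 585 genes set control tumours 1 and 4 and propranolol tumours 1 and 4 against the rest. It keeps every number pair whole (1 and 4 against 2 and 3) and parts 4 of the 5 tumours with the highest T cell scores from the rest. This split was picked because its count was the highest of the 35. Whether the count reflects the number pairs, the T cell content or chance was not tested. With the replicate block only the 8 splits that part every number pair apply. They are too few for a share under 0.05: as many lists as the real 12 were found in 3 of them (highest other 19), and the real gene count of 0 is again reached by all 8 by definition (highest other 133).

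The spread of the T cell list between tumours, 4.04 on the log2 scale from lowest to highest, was larger than the difference between groups. If a lower share of tumour cells raised every other cell type alike, the endothelial and fibroblast lists would rise with the T cell list. They did not, with slopes of -0.05 (SE 0.05) and -0.08 (SE 0.06) and at most 0.0263 with any tumour left out. The slopes speak only to such an even rise, and a lower share made up by immune cells alone is not tested by them. Whether the tumour cells express the fibroblast and matrix genes themselves was not tested either. RNA quality, read as the mitochondrial share of counts, stays open as a partial cause. The share did not track the list (exact permutation p of Pearson's r = 0.491, r = -0.29; Spearman's rho -0.02, permutation p = 0.977; r = -0.20 without the 2 tumours farthest from the median list score), yet it differed 1.32-fold between the tumours with the highest and lowest list scores. A difference in T cell infiltration between tumours, with or without propranolol, may account for the spread and is not tested by these data, in which propranolol tumours lie at both ends.

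Skeletal muscle transcripts in control tumour 4 may come from muscle tissue carried into 1 tumour sample. The 13 list members in the table summed to 1050 CPM (of library totals without TMM scaling) there and to 8.59 to 119 CPM in the other tumours, with 118.5 CPM in propranolol tumour 1. The muscle genes outside the list were highest in control tumour 4 in 9 of 9 cases, but any source of muscle transcripts would give that count, so it does not decide for muscle tissue carried into 1 tumour sample. Propranolol tumour 1 was second highest, by the same CPM, for Neb (6.22 CPM), Ryr1 (6.92 CPM) and Actn2 (3.14 CPM), so the transcripts are not limited to control tumour 4. The source stays open, and no biological explanation was tested.

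The lower erythroid list in propranolol tumours differed by -0.99, and by -0.56 without control tumour 4, where it passed camera at the preset correlation of 0.01 (adjusted p = 0.00290). That test was set to exclude blood in control tumour 4 alone, but the members move together (estimated correlation 0.932), so the preset value was too low for it. With an estimated correlation the adjusted p without that tumour was 0.912, and exact permutation of the score gave p = 0.229. Blood in control tumour 4 therefore stays open, as do an effect of propranolol on blood content and a difference in how tumours were bled or frozen.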

How the results depend on the processing

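Every alternative here was planned beforehand. The count of genes past the threshold was 0 with edgeR and under all 21 alternatives, while the count at an unadjusted p under 0.05 moved from 273 to 717 with the replicate block, 597 with quality weights, 150 at a mean CPM of at least 10, 459 without propranolol tumour 2, 1017 without propranolol tumour 3 and 134 without propranolol tumour 1. Scaling choices moved the median log2 fold change by at most 0.00278. Of 28 lists, 8 passed camera, also with RLE factors, library size only, no filter and a prior count of 0.5; 0 passed with an estimated correlation and 0 with fry; 12 passed with the replicate block, which changed no call other than the 4 added. Leaving out 1 tumour gave 2 to 19 lists: 2 without propranolol tumour 4, 5 without control tumour 3 and 19 without propranolol tumour 3. The cause was not tested.

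No named gene passed in any of 1460 comparisons with alternatives, and 70 of 80 kept their sign in all. Signs turned with quality weights for Atp2a1 (0.22), Ckm (0.78), Hspb1 (0.51), Car9 (-0.0359) and Adm (-0.00426), with limma-voom for Ctla4 (-0.81) and Foxp3 (-0.37), and with the block for Ctla4 (-0.0517) and Foxp3 (-0.20). Leaving out 1 tumour gave ranges through 0 for Atp2a1 (-4.76 to 0.45), Ckm (-5.06 to 0.0738), Hspb1 (-1.58 to 0.52), Car9 (-0.52 to 1.59), Adm (-0.14 to 0.81), Hgf (-0.0410 to 0.63), Krt8 (-1.76 to 0.61), Tigit (-0.10 to 0.27), Ctla4 (-0.26 to 0.58) and Foxp3 (-0.65 to 0.43).

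Of the lists, 14 of 28 kept their sign in all alternatives. Leaving out 1 tumour gave ranges through 0 for regulatory T cells (-0.0925 to 0.48), B and plasma cells (-0.14 to 0.75), neutrophils (-0.0583 to 0.43), mast cells (-0.00695 to 0.79), type I interferon (-0.0308 to 0.55), beta-adrenergic signalling (-0.0326 to 0.0585), cAMP-induced genes (-0.22 to 0.0714), endothelium (-0.0834 to 0.12), angiogenic factors (-0.0800 to 0.12), hypoxia (-0.27 to 0.47), glycolysis (-0.12 to 0.25), p53 targets (-0.0397 to 0.0314; with RLE factors 2.90e-04), skeletal muscle (-1.78 to 0.63) and stress genes (-0.34 to 0.0307). Without propranolol tumour 4 the 5 immune lists had adjusted p of 0.423 to 0.850. In counts simulated with these depths and dispersions, 57% of 2-fold changes were recovered, so smaller differences were not reliably detectable. That rate is an average over independent genes drawn at random. Larger differences could also be missed in genes that vary widely between tumours, such as Cd8a. Its log2 fold change of 2.16 (SE 1.01) had an edgeR adjusted p of 0.999.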

Other observations

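The tests in this part that were chosen after the result was seen are the comparison of exhaustion genes with T cell genes, the correlations with the T cell list, the count of genes whose groups do not overlap and the antigen receptor genes; the 2 tests of spread were set before.

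The constant-region genes of the T cell and antibody receptors were singled out after their values were seen. Trac, the constant region of the alpha chain, had 13.9 and 17.5 CPM in propranolol tumours 1 and 4, 0.493 CPM in propranolol tumour 3 and 1 to 4.52 CPM in controls (log2 fold change 1.66, SE 0.90). Trbc1 and Trbc2, the near-identical beta chain constant regions, had log2 fold changes of 1.42 (SE 0.89) and 1.76 (SE 0.86), and Trdc, the delta chain constant region, 0.80 (SE 0.86). Igha, the constant region of IgA, was at 1.29 CPM in propranolol tumour 3 and 79.1 CPM in propranolol tumour 1, and at 8.13 to 35.9 CPM in controls. Ighm, the constant region of IgM, was at 2.09 CPM in propranolol tumour 3 and 61.1 CPM in propranolol tumour 4, and at 5.13 to 37.7 CPM in controls. None passed edgeR's threshold (adjusted p 0.999 for each). C1ra, the close relative of C1rb, had a log2 fold change of 0.68 (SE 0.36).

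Across the 8 tumours, the T cell list was compared with the other 27 lists, with which it shares 0 genes. The relation passed Benjamini-Hochberg adjustment by both Pearson's r and Spearman's rho for 9 lists, and all 9 were positive. The closest was MHC class II presentation (r = 0.990, permutation p = 4.96e-05, adjusted 0.00112; rho = 0.976, permutation p = 3.97e-04, adjusted 0.00357; r = 0.992 without the 2 tumours farthest from the median, propranolol tumours 3 and 4). Exhaustion and inhibitory receptors followed nearly as closely (r = 0.975, permutation p = 9.92e-05, adjusted 0.00112; rho = 0.976, permutation p = 3.97e-04, adjusted 0.00357; r = 0.964 without those 2). Cytotoxic effectors, NK, B and plasma, macrophage, mast and dendritic markers and the interferon gamma response made up the other 7, with r of 0.871 to 0.986. Without those 2 tumours r was 0.722 for mast and 0.818 for dendritic markers, and 0.915 to 0.968 for the rest of the 7. Hypoxia response ran the other way without passing (r = -0.62, permutation p = 0.102, adjusted 0.196; rho = -0.40, permutation p = 0.327, adjusted 0.490; r = -0.71 without those 2).

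A hypothesis was that exhaustion genes are lower per T cell transcript in propranolol tumours. The exhaustion score minus the T cell score was 0.13 ± 0.27 in control and -0.13 ± 0.79 in propranolol tumours (SD, n = 4), a difference of -0.26 with an exact permutation p = 0.543, which cannot be told apart from 0 with this spread. Propranolol tumours 1, 2 and 4, at -0.57, -0.43 and -0.57, lay below every control tumour, and propranolol tumour 3 lay above all at 1.05. Without propranolol tumour 3 the difference was -0.66 (exact permutation p = 0.0286, not adjusted over the fits). With any other tumour left out it was -0.12 to -0.32 (exact permutation p of 0.543 to 0.914). The measure was highest in the tumours with the fewest T cell transcripts, propranolol tumour 3 and control tumour 3 (1.05 and 0.54, at T cell scores of -2.15 and -1.24), and lowest in propranolol tumours 1 and 4, with the most. The measure subtracts the T cell score, so part of this order is built in. Some exhaustion list members also did not fall in step with T cell transcripts. In propranolol tumour 3, with 1.05 CPM of Cd8a, Nr4a2 was at 44.9, Entpd1 at 18.7 and Tigit at 8.93 CPM. Prdm1 was highest there and in control tumour 3, at 33.8 and 22.1 CPM. Other members, such as Pdcd1 at 0.493 CPM and Lag3 at 1.54 CPM, were low in propranolol tumour 3. The measure is therefore not one of T cells alone. At similar T cell scores, propranolol tumour 2 (0.17) was at -0.43 and control tumours 1 (0.21) and 4 (0.08) at -0.02. Propranolol tumour 2 thus lay below controls of like T cell content, but 1 tumour does not decide the question. The hypothesis stays open. Over 7 such measures, Ctla4 relative to Cd8a gave the smallest value, -1.73 on the log2 scale (exact permutation p = 0.0286, the smallest the design allows, adjusted p = 0.2). Ctla4 was at 0 CPM in propranolol tumour 3, so that tumour's ratio, and the size of the difference, depend on the prior count of 2. For Pdcd1 relative to Cd8a the difference was -0.14 (exact permutation p = 0.686, adjusted p = 0.8).

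A second hypothesis was that propranolol tumours vary more than control tumours. The SD of the list score was larger in propranolol tumours for 25 of 28 lists, with a mean log2 ratio of SDs of 0.78. Of the 35 splits of the tumours, 3 gave as high a ratio (highest other 0.956), so chance cannot be excluded over these. Over all genes, 58.9% had the larger SD in propranolol tumours, and 18 of the 35 splits gave as high a share (highest other 75.8%). Among the 8 splits that part every number pair the real one was highest in both measures (0.783 against at most 0.704, and 58.9% against at most 57.6%), but 8 splits are too few for a share under 0.05.

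Genes whose 4 propranolol values all lay above all 4 control values numbered 100, and those lying below numbered 128. Together they are 1.63% of the tested genes, where chance gives 2.86%.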
